A study of Arabidopsis thaliana with 35 samples.

How the data were processed

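The deposited table held 35 arrays and 22810 probe sets per array. Per the labels, the arrays carried biotin-labelled cRNA made from 250 ng of total RNA, drawn from leaves of Arabidopsis thaliana plants aged 4 weeks that grew at 22 °C with 16 h of light. The infected groups carry the label words AB, for fungi, and ES4, for bacteria, which were used here as written. The deposited unit was signal intensity on a linear scale, which per the submitters' processing notes came from MAS5. The version and settings of MAS5 were not given in the sources used here. Of the 35 arrays, 12 had been deposited with a 2% trimmed mean of 500 and 23 had not, with trimmed means from 15.7 to 131. The 12 were the arrays of taf4bint, of the overexpression line and of the Col-0 sets paired with them. Every array was therefore scaled here to a 2% trimmed mean of 500.

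Scaled values were transformed as log2 of the value plus 5.56, the 10th percentile of the table. Where the mean signal of a group lay under 5.56, the fold is set largely by this pseudocount and is a lower bound, which applies to AT1G33760 in the infected groups, to AT3G51470 and AT2G37580 in the Col-0 set for taf4bprm, to AT4G19370 in taf4bprm, to GAT1_2.1 in the Col-0 set for the line, to GH9B8 and AT1G09500 before infection of Col-0, and to AT1G13650 before infection of taf4bprm. The same applies to AT2G35730 in uninfected taf4bprm, with a signal of 2.26. The 64 Affymetrix control probe sets were left out of the tests and served for the actin and GAPDH ratios of 3' to 5' signal. Probe sets below the 30th percentile of mean log2 signal were dropped, which left 15922 of 22746 for testing. The probe table named 1 gene for 8710 of the tested probe sets, several genes for 325, and no gene for 6887. Gene symbols came from matching the named loci to the TAIR10.1 RefSeq annotation, and a locus without a symbol is given by its locus name. TAF4B, TAF4 and CPR5 were not analysed here, because the probe table names no probe set for them.

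The 35 arrays formed 12 groups of 3 arrays, except for the Col-0 set paired with the double mutant, which had 2. One linear model in limma held a coefficient for each group, with 23 residual degrees of freedom and empirical Bayes moderation with a mean-variance trend. The spread behind each SE and p-value is therefore pooled over all 12 groups, not taken from the groups compared alone. Each of 13 comparisons was a contrast in this model, and all p-values printed for probe sets are from limma's moderated test, adjusted by the Benjamini-Hochberg method over the 15922 probe sets tested. A probe set with an adjusted p under 0.05 was called higher or lower. Each line was compared with the Col-0 set that the labels pair with it. The labels name no uninfected control for the infected arrays, so the Col-0 set paired with taf4bprm served for infected Col-0 and the uninfected taf4bprm arrays served for infected taf4bprm. Differences of responses were tested as contrasts of contrasts. Set tests used limma's camera with a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the lists of a comparison. They were run for lists with at least 3 members left after the filter. Of the gene lists, 27 were written before the data were examined and 24 gene families were chosen afterwards. The families named below are plastid- and mitochondrion-encoded genes, UDP-glycosyltransferases, cytochromes P450, XTH, RALF-like, calmodulin-like, U-box and autophagy genes. They were chosen after the values were seen, so their set tests are not independent of those values. The probe table named only 60 of the 436 genes written into the lists, so a list count covers its measured members alone, such as 3 of 28 salicylic acid genes, 3 of 21 pattern-triggered immunity genes, 3 of 16 Calvin cycle genes and 5 of 37 light reaction genes.

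The genes named in each comparison are the 6 highest and the 6 lowest log2 changes among single-gene probe sets past the threshold whose groups do not overlap, without the overlap condition for differences of responses. They also include up to 3 members of each list written beforehand with the largest absolute change past the threshold, and the 6 smallest p-values where fewer than 12 such probe sets passed. Where a gene had several probe sets, the one with the highest mean signal was used. Members of the gene families chosen afterwards, genes shared between comparisons and genes followed across Col-0 sets were picked after the values were seen.

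The processing was repeated with quantile normalization, with no pseudocount, with the 25th percentile (33.4) as pseudocount, without the filter, with only the arrays of the groups compared, with a block for the replicate number, with each array left out in turn, with all 11 uninfected Col-0 arrays as control and, for infection, with each other Col-0 set as control. These settings were chosen before the data were examined. The test of infection calls against each Col-0 set, which uses the same alternative controls, was chosen only after the results were seen. A fit to the values as deposited, without scaling, was added afterwards. Named genes were not followed in that fit, so counts of named genes that passed under every setting leave it out. In a test of recovery, arrays were simulated from the fitted group means with independent normal noise at the model's own spread. On the taf4bprm comparison, 52% of 100 probe sets given a true log2 change of 1 were called, 84% were called at a log2 change of 2, and 5 calls were false. The simulated arrays meet the model's assumptions, so this does not show how often calls are false in the real arrays. The work used R 4.3.3 and limma 3.58.1.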

Results

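Leaf RNA was measured on 35 arrays of Arabidopsis thaliana in 12 groups. The uninfected groups were taf4bprm, taf4bint, a Taf4b overexpression line, a taf4bprm cpr5 double mutant and 4 sets of Col-0 arrays, each set paired by the labels with 1 of the lines. The labels of the paired Col-0 sets speak of overexpression lines and double mutant lines, so these groups may each hold more than 1 line. The infected groups were Col-0 and taf4bprm, each with the infections labelled AB and ES4. Titles call the arrays of a group biological replicates, but nothing says that they came from separate plants, so p-values measure only the spread between these samples, which may be technical. Principal components 1 and 2 held 24.6% and 20.5% of the variance. Along component 2, the 3 taf4bprm arrays (88.7 to 104) lay beside their own Col-0 set (91.6 to 102), while the other 3 Col-0 sets lay between −33.0 and −1.43. All 12 infected arrays lay at 42.0 or above on component 1. The 2 arrays of the Col-0 set for the double mutant correlated at 0.84, the lowest value among replicates. The actin ratio of 3' to 5' signal averaged 4.55 in the Col-0 set for taf4bprm, 3.67 in taf4bprm and 6.95 in the double mutant. It was 20.9, 14.8 and 18.3 in the Col-0 sets for taf4bint, for the overexpression line and for the double mutant, 23.46 in taf4bint and 14.6 in the overexpression line. In the infected groups the ratio averaged 3.84 (Col-0, AB), 4.49 (Col-0, ES4), 6.44 (taf4bprm, AB) and 3.40 (taf4bprm, ES4).

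**Figure D1:**
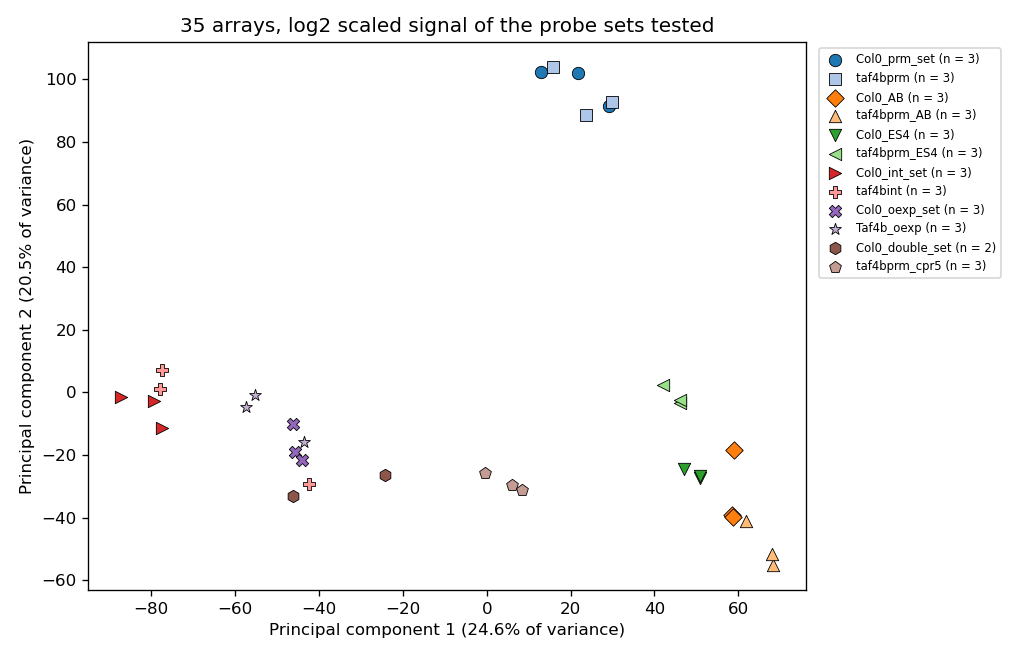
Scores of the 35 arrays on principal components 1 (24.6% of variance, horizontal) and 2 (20.5%, vertical). Each point is 1 array, with color and marker by group.

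TAF4B was not analysed here, so the comparison of taf4bprm with Col-0 gives no value for the mutated gene. The protein phosphatase gene AT3G51470 was at least 21.9-fold higher in taf4bprm (log2 4.45 ± 0.38 SE, adjusted p = 9.7e-09, n = 3 against 3), with a signal of 223 ± 28.4 against 5.02 ± 2.50 (mean ± SD). The auxin-conjugating enzyme gene GH3.3 rose 11.7-fold (log2 3.55 ± 0.72, adjusted p = 0.0011) and the Aux/IAA gene IAA29 rose by log2 1.87 ± 0.52. The expansin-like gene EXLA2 rose 7.34-fold (log2 2.88 ± 0.52), and AT3G58540, AT2G37580 and AT3G02820 rose by log2 3.18, 3.15 and 3.00. The lowest changes were those of AT3G21080 (19.8-fold lower, log2 −4.31 ± 0.88), AT1G26420 (log2 −3.87 ± 0.79), AT4G19370 (−3.79), AT3G18250 (−3.71), the glycosyltransferase UGT76E12 (−3.52 ± 1.09) and AT4G12500 (−3.49 ± 0.71).

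In taf4bprm all 3 measured Calvin cycle genes rose, also when adjusted over the list alone, with a median log2 change of 1.22: phosphoribulokinase PRK rose 2.48-fold (log2 1.31 ± 0.14, adjusted p = 6.1e-07), SBPASE by log2 1.22 ± 0.28 and rubisco activase RCA by 0.51 ± 0.15. Camera with preset correlation gave adjusted p = 5.2e-04 for this list, and adjusted p = 0.175 with an estimated correlation. Of 5 light reaction genes 3 rose and 0 fell, counts that stayed when adjusted over the list alone: ATPC1 (log2 0.79 ± 0.13), PSAN (0.66 ± 0.19) and LHCB4.1 (0.41 ± 0.13). Camera gave this list adjusted p = 0.0111, and adjusted p = 0.426 with an estimated correlation. Of 3 auxin genes 2 rose while WES1 did not pass (log2 −0.096), the auxin list did not pass camera (adjusted p = 0.0725), and of 4 ABA and cold genes COR47 alone passed (log2 0.86 ± 0.25). The glucosinolate glucosyltransferase UGT74B1 fell by log2 −1.04 ± 0.24 and the tryptophan synthesis gene AT2G04400 by −1.39 ± 0.27. The reference gene AT4G34270 was lower by log2 −0.56 ± 0.17. None of the measured salicylic acid, pattern-triggered immunity, ethylene, heat, endoplasmic reticulum and cell wall genes passed. Among families chosen after the values were seen, 9 of 13 cytochromes P450 fell and 0 rose (median log2 −1.23), led by CYP71B23 (−3.05 ± 0.53) and CYP71B36 (−2.45 ± 0.47). All of these 13 but CYP84A4 and CYP78A9 belong to the CYP71B subfamily, so the counts do not stand for cytochromes P450 at large. Camera gave the P450 genes adjusted p = 8.3e-06, and adjusted p = 0.0129 with an estimated correlation. Of 5 XTH cell wall enzymes 4 rose, with XTH32 at log2 2.32 ± 0.36, and camera gave adjusted p = 0.0073, or adjusted p = 0.102 with an estimated correlation.

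In all, 1253 probe sets were higher and 1328 lower in taf4bprm by limma's moderated test with Benjamini-Hochberg adjustment, 2581 of 15922, against 4690 with an unadjusted p under 0.05. Against all 11 uninfected Col-0 arrays the photosynthesis direction turned: PRK was at log2 −0.18, SBPASE at −0.20, RCA at −0.28, ATPC1 at −0.67, PSAN at −0.80 and LHCB4.1 at −0.12, and AT2G37580 turned as well (−0.028). Of 23 named genes, 9 passed in the same direction under every setting.

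In taf4bint, the lowest changes were those of AT2G18210 (14.3-fold lower, log2 −3.84 ± 0.78), AT4G01390 (−3.42), AT5G28430 (10.1-fold lower, −3.33 ± 0.44, adjusted p = 1.2e-04, n = 3 against 3) and AT1G33760, an AP2/ERF factor (−3.16 ± 0.63). AT5G22580 (−2.73 ± 0.42), AT5G12940 (−2.72) and the expansin EXPA8 (−2.24 ± 0.54) also fell. The highest were AT1G23000 (log2 2.67 ± 0.64), AT5G50915 (2.58 ± 0.43, adjusted p = 0.0011), AT1G23205 (2.55), AT5G24080 (2.53), AT4G23680 (2.49) and AT3G28500 (2.47). UGT74B1 fell by log2 −1.01 ± 0.24. The immune signalling gene SAG101 fell by log2 −0.96 ± 0.28 (adjusted p = 0.046), 1 of 3 measured salicylic acid genes, or 2 of 3 adjusted over the list alone. Camera gave the salicylic acid list adjusted p = 0.040, and adjusted p = 0.294 with an estimated correlation. Of the ethylene genes 0 passed, and 2 fell when adjusted over the list alone. Of 8 plant U-box ligases, PUB25 (−1.52 ± 0.27) and PUB23 (−1.83 ± 0.47) fell. Limma's moderated test called 247 higher and 410 lower, 657 in all, with 3035 under an unadjusted p of 0.05. Without replicate 2 or 3 of its Col-0 set 237 or 230 were called, and 0 of 15 named genes passed under every setting. With only the 6 arrays compared, 14 calls were left, and of the named genes AT5G28430 alone still passed.

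The overexpression line showed its highest changes in AT1G09500 (31.7-fold, log2 4.99 ± 0.99, adjusted p = 0.0062, n = 3 against 3), GAT1_2.1 (4.15), AT2G38240 (3.85), the MADS box gene AGL42 (10.7-fold, 3.43 ± 0.43, adjusted p = 1.5e-04), the late embryogenesis gene LEA4-5 (3.35 ± 0.75) and AT1G74010 (3.28). The lowest were AT1G33760 (log2 −3.35 ± 0.63), AT4G38660 (−3.29 ± 0.50), AT3G54400 (−3.26 ± 0.46), EXO (−3.11 ± 0.58), HLL (−2.70) and AT4G35320 (−2.58). Calreticulin CRT1b fell by log2 −0.83 ± 0.20 as 1 of 3 endoplasmic reticulum genes. Of 6 RALF-like peptide genes, a family chosen after the values were seen, 4 fell, 5 when adjusted over the list alone. Their median was log2 −0.88, with RALFL22 at −1.40 ± 0.33 and RALFL33 at −1.02 ± 0.15. Camera gave this family adjusted p = 1.0e-05, and adjusted p = 0.0560 with an estimated correlation. Of 8 autophagy genes ATG8H (1.32 ± 0.35) and ATG8D (0.71 ± 0.17) rose, and 6 rose when adjusted over the list alone. By limma's moderated test 407 probe sets were higher and 479 lower, 886 in all, with 3474 under an unadjusted p of 0.05. Replicate 3 of the line correlated at 0.955 with the mean of its Col-0 set and at 0.928 with the other 2 replicates of the line. Without that array 2162 probe sets were called, without replicate 1 or 2 of the line 146 or 101, and without 1 of the Col-0 arrays 450 to 494. With only the 6 arrays compared 10 were called, and 0 of 13 named genes passed under every setting.

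In the taf4bprm cpr5 double mutant, plastid-encoded genes were lower than in its Col-0 set. Of 69 such genes, a family chosen after the values were seen, 64 fell and 0 rose, 67 fell when adjusted over the list alone, and the median log2 change was −1.63. The NADH dehydrogenase subunit gene ndhD fell 21.3-fold (log2 −4.42 ± 0.24, adjusted p = 5.3e-13, n = 3 against 2), atpF by log2 −3.71 ± 0.31 and the photosystem II gene psbA by −3.07 ± 0.42. Camera gave adjusted p = 1.5e-53, and adjusted p = 0.00797 with an estimated correlation. Mitochondrion-encoded respiratory genes fell in 5 of 12 cases, with nad4 at log2 −2.63 ± 0.31. The mean log2 signal of the 69 plastid genes was 11.18 in the double mutant, 12.95 in its own Col-0 set, and 12.37, 11.71 and 11.24 in the Col-0 sets for taf4bint, taf4bprm and the overexpression line. Against these other 3 Col-0 sets, 55, 31 and 14 of the 69 genes were lower in the double mutant, with median log2 changes of −0.96, −0.45 and −0.11.

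**Figure D2:**
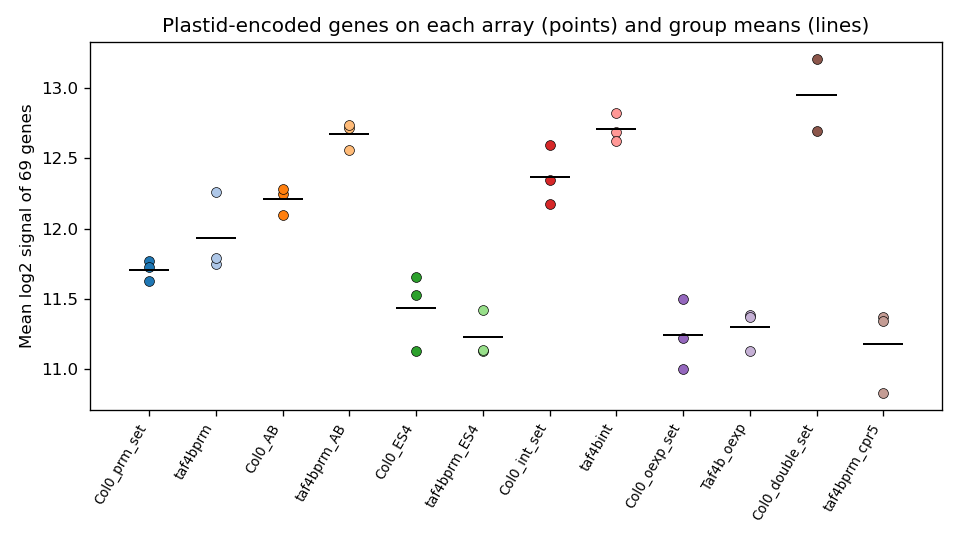
Mean log2 signal of 69 plastid-encoded genes (vertical) on each array, by group. Points are arrays and lines are group means.

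Among the lowest changes in the double mutant, AT1G33760 fell 36.9-fold (log2 −5.20 ± 0.71), AT3G02840 35.5-fold (−5.15 ± 0.64), AT4G27654 by log2 −4.92, AT4G29780 by −4.77 and the AP2/ERF gene ORA47 by −4.40 ± 0.46. The zinc finger gene STZ fell by log2 −2.15 ± 0.42 (adjusted p = 3.9e-04), WRKY53 by −1.73 ± 0.46, GRX480 by −1.61 ± 0.57, BZIP60 by −1.58 ± 0.31 and WRKY22 by −0.88. Of 3 salicylic acid genes 2 fell, and of 7 calmodulin-like genes 4 fell (median log2 −1.04), with CML37 at −3.50 ± 0.79 and CML38 at −3.38 ± 0.50. Camera gave the calmodulin-like genes adjusted p = 0.00797 with an estimated correlation. The U-box ligases PUB22 (−3.20 ± 0.52), PUB23 (−2.94 ± 0.53) and PUB24 (−1.34 ± 0.34) fell, 3 of 8. None of the 11 lists tested that were written beforehand passed camera in this comparison. In the nucleus-encoded photosynthesis lists, 2 of 3 Calvin cycle genes fell (SBPASE −1.26 ± 0.32, RCA −0.50) and 2 of 5 light reaction genes fell (ATPC1 −0.90 ± 0.15, PSAE-1 −0.59). The trichome gene TRY fell by log2 −2.41 ± 0.70 and the flavonol glucosyltransferase UGT78D2 by −1.41. Without 1 or the other of the 2 control arrays RCA, SBPASE, PSAE-1, WRKY22, WRKY53, GRX480 and TRY no longer passed. Against all 11 Col-0 arrays TRY turned to log2 0.17, and quantile normalization turned PSAE-1 to 0.047.

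Genes that rose in the double mutant were led by AT4G16260 (log2 3.81 ± 1.12), AT1G17520 (11.6-fold, 3.54 ± 0.34, adjusted p = 2.1e-08), the Mediator subunit MED6 (10.7-fold, 3.42 ± 0.45, adjusted p = 2.8e-06), AT4G12500 (3.40 ± 0.79), GH3.3 (3.34 ± 0.80) and AT4G28180 (3.31). Without replicate 1 of the 2 control arrays GH3.3 (log2 1.19), AT4G16260 (0.997) and AT4G12500 (1.98) no longer passed, while AT1G17520, MED6 and AT4G28180 did. Auxin genes rose in 2 of 3 cases, 3 of 3 adjusted over the list alone, with WES1 at log2 2.34 ± 0.55, but without that array neither GH3.3 nor WES1 (0.69) passed. COR15A (1.72) and COR15B (1.54) rose among 4 ABA and cold genes, 3 of 4 adjusted over the list alone, and neither passed without that array. The clock gene GI rose by log2 2.25 ± 0.42, or by 0.62 without that array, the immune receptor EFR rose 4.29-fold but did not pass without the other control array, and EIN3 rose by 0.99 ± 0.20 but stood at −0.037 against all 11 Col-0 arrays. The reference gene AT2G28390 rose by log2 1.12. With 2 control arrays, 2691 probe sets were higher and 1359 lower, 4050 in all, around a median shift of log2 +0.14, and every call higher lay above that shift. The values as deposited gave 176 higher and 1510 lower. With only the 5 arrays compared, 121 were called, among them ndhD, ORA47, AT3G02840, AT4G27654 and AT4G29780, and against all 11 Col-0 arrays 1451 were called. Of 30 named genes, 3 passed in the same direction under every setting.

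**Figure D3:**
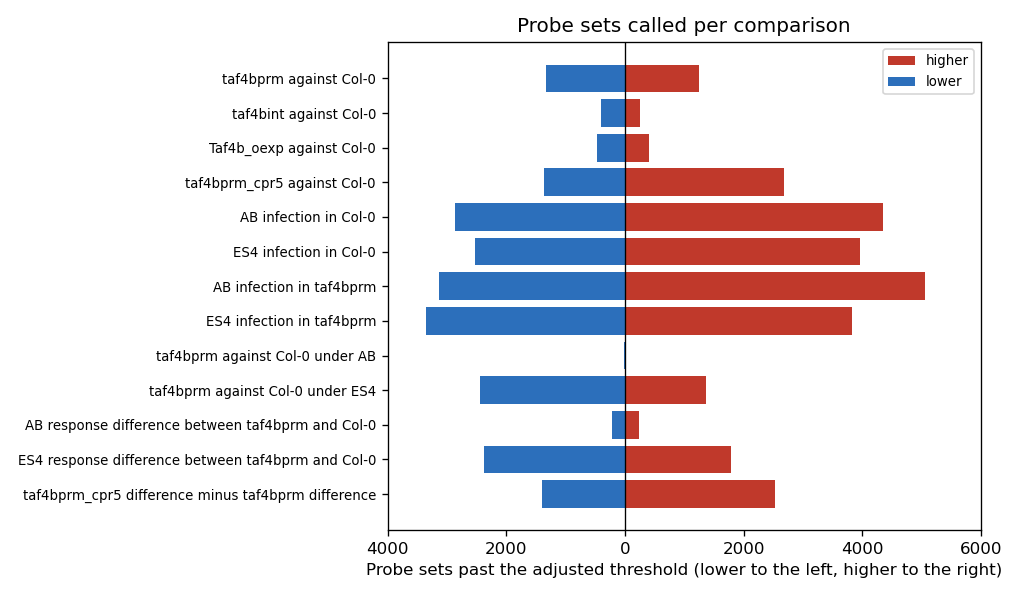
Probe sets past the adjusted threshold in each of 13 comparisons, with lower calls to the left and higher calls to the right. Bars are counts of probe sets.

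Changes in taf4bprm and taf4bint, which share no array, had a correlation of 0.02 (Spearman 0.04) across all probe sets, where genes are not independent replicates, while calls in the same direction exceeded the number expected. Both raised 46 probe sets against 19.4 expected and both lowered 66 against 34.2, while 37 and 20 went in opposite directions against 32.3 and 20.6. Picked after the values were seen, AT1G80130 (log2 −1.80 in taf4bprm and −1.84 in taf4bint), AT1G51920 (−2.79 and −1.67), AT1G02360 (−2.15 and −1.59) and ATPMEPCRB (−1.67 and −1.77) fell in both, AT4G34950 rose in both (2.21 and 1.46), and XTH18 rose in taf4bprm (1.58) and fell in taf4bint (−1.69). The overexpression line ran opposite to taf4bprm with a correlation of −0.22: 89 probe sets higher in taf4bprm were lower in the line against 37.7 expected, and 76 lower in taf4bprm were higher against 33.9. Both raised 15 against 32.0 expected and both lowered 17 against 40.0. EXLA2 was at log2 2.88 in taf4bprm and −1.79 in the line, AT4G38660 at 1.65 and −3.29, and AT1G09750 at 2.07 and −1.96. Between taf4bint and the line the correlation was 0.23, with 27 higher in both against 6.31 expected and 21 lower in both against 12.3, among them AT1G33760 (−3.16 and −3.35) and AT1G51920 (−1.67 and −2.34). These groups and their Col-0 sets are the arrays that were deposited scaled. Between taf4bprm and the double mutant the correlation was −0.06, with 188 higher in both against 212 expected, 95 lower in both against 113, and 288 lower in taf4bprm but higher in the double mutant against 224. AT4G12500 (−3.49 and 3.40), AT4G12490 (−3.12 and 3.36) and AT1G26420 (−3.87 and 2.65) were of the last kind, while GH3.3 rose in both.

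With infection AB in Col-0, WRKY22 fell 16.8-fold (log2 −4.07 ± 0.28, adjusted p = 9.9e-12, n = 3 against 3), STZ 10.0-fold (−3.33 ± 0.37), WRKY53 by log2 −3.18 ± 0.41 (adjusted p = 4.4e-07), SAG101 by −2.63 ± 0.28, WRKY6 by −2.31, GRX480 by −1.61 and the receptor kinase partner BIK1 by −1.31. Of 3 salicylic acid genes 3 fell (median log2 −2.63) with camera adjusted p = 0.0055, and adjusted p = 0.0913 with an estimated correlation. Pattern-triggered immunity genes fell in 2 of 3 cases with camera adjusted p = 0.0119, and adjusted p = 0.129 with an estimated correlation. All 4 ABA and cold genes fell, with LTI30 52.4-fold lower (−5.71 ± 0.54), COR15A at −2.78 and COR15B at −2.38; camera gave adjusted p = 4.5e-04, and adjusted p = 0.0913 with an estimated correlation. Calmodulin-like genes, a family chosen after the values were seen, included CML38 at log2 −4.17 ± 0.45 and CML23 at −3.01 ± 0.39. They fell in 5 of 7 cases (median log2 −2.41, camera adjusted p = 0.0139 with an estimated correlation). Against the Col-0 sets for taf4bint, the line and the double mutant 4, 3 and 4 fell and 0, 1 and 1 rose. AT1G33760, with a signal of 2.52 under AB, fell at least 80.5-fold (−6.33 ± 0.63), and AT5G06570 (−5.70), AT1G15010 (−5.49), AT2G27080 (−5.29) and AT1G22810 (−5.04) followed.

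With AB the defensins PDF1.2b (log2 4.80 ± 0.92) and PDF1.2 (4.03 ± 1.03) rose, 2 of 3 ethylene and necrotroph defence genes, while the third, EIN3, fell. Against the Col-0 sets for taf4bint and the overexpression line 0 genes of that list rose, and against the set for the double mutant 3 did. PDF1.2b was at log2 2.08 and PDF1.2 at 1.57 against the set for taf4bint, and at −0.74 and −1.55 against the set for the line. The thionin THI2.1 (3.06 ± 1.03) rose, as did the β-glucosidase PYK10 (45.7-fold, 5.52 ± 1.02). The largest rise was that of AT3G33066 (138-fold, 7.11 ± 1.11), followed by AT4G19430 (5.83), AOR (5.35), GH9B8 (5.26) and AT4G16260 (5.10). Glucosinolate genes AT2G31790 (3.23), BCAT4 (2.54) and UGT74B1 (1.66) rose, as did EXPA8 (3.91), 1 of the cell wall genes, 3 of which rose when adjusted over the list alone. Against the sets for taf4bint, the line and the double mutant BCAT4 turned to log2 −1.49, −1.12 and −1.47, and 0 cell wall genes rose. Of 5 heat genes AT1G53540 (2.14) and AT5G37670 (1.53) rose, and in the endoplasmic reticulum list CRT1b (1.47 ± 0.20) and ATERDJ3B (1.22) rose while BZIP60 fell (−1.38). All 3 Calvin cycle genes rose (PRK 1.85 ± 0.14, SBPASE 1.41, RCA 0.40), with camera adjusted p = 0.0274, and adjusted p = 0.311 with an estimated correlation. Light reaction genes rose in 3 cases (LHCB4.2 4.29-fold, ATPC1 log2 1.22, PSAN 1.00) and fell in 1. Against the other 3 Col-0 sets 0 genes of these 2 lists rose, while 1, 1 and 2 Calvin cycle genes and 5, 5 and 4 light reaction genes fell. TRY (2.26) and UGT78D2 (1.43) rose, EIN3 (−1.01) and the sucrose transporter SWEET11 (−1.38) fell, and of the reference genes GAPC2 rose (0.47) and AT2G28390 (−0.45) and PEX4 (−0.55) fell. Against at least 1 other Col-0 set TRY, UGT78D2, EIN3, WRKY6, GAPC2 and AT2G28390 stood in the opposite direction. In all 4349 probe sets were higher and 2873 lower, 7222 in all, around a median shift of log2 +0.17, with all higher calls above the shift. The values as deposited gave 11849 higher and 441 lower, and 15 of 46 named genes passed under every other setting.

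With infection ES4 in Col-0, STZ fell 12.4-fold (log2 −3.64 ± 0.37, adjusted p = 9.3e-09, n = 3 against 3), WRKY22 by log2 −3.41 ± 0.28, WRKY53 by −3.03 ± 0.41, SAG101 by −2.25 ± 0.28, EFR by −1.63, WRKY6 by −1.60 and BIK1 by −1.44. Salicylic acid genes fell in 2 of 3 cases (camera adjusted p = 0.0298, and adjusted p = 0.183 with an estimated correlation) and pattern-triggered immunity genes in 3 of 3 (camera adjusted p = 0.0167, and adjusted p = 0.183 with an estimated correlation), but in 2, 0 and 2 against the Col-0 sets for taf4bint, the line and the double mutant. Calmodulin-like genes, a family chosen after the values were seen, included CML38 at log2 −4.30 ± 0.45. They fell in 6 of 7 cases (median log2 −2.21, camera adjusted p = 0.00328 with an estimated correlation), but in 4, 4 and 4 against those other Col-0 sets. AT1G33760, with a signal of 1.72 under ES4, fell at least 89.3-fold (−6.48 ± 0.63), and AT5G48430 (−6.24), AT2G44370 (−5.90), AT1G77640 (−5.64), AT2G17740 (−5.62) and the cold gene COR27 (−5.47 ± 0.28) were next. Against those 3 Col-0 sets AT2G17740 turned to log2 0.43, 0.66 and 0.32, and AT5G48430 turned to 0.046 and 2.01 against the first 2. The highest were AT1G09500 (6.23), the glutathione transferase GSTU20 (6.03 ± 0.87), GH9B8 (5.89), UGT78D1 (5.48), PYK10 (5.48 ± 1.02) and AT1G47400 (5.17). GH3.3 rose 11.8-fold (3.56 ± 0.72, adjusted p = 2.1e-04) and IAA29 by log2 2.96, 2 of 3 auxin genes. PDF1.2b (3.99), PDF1.2 (3.70), BCAT4 (3.99), AT2G31790 (3.61 ± 0.29), UGT74B1 (1.56), the anthocyanin gene DFR (3.51) and UGT78D2 (1.90) rose. Against the Col-0 set for the overexpression line PDF1.2b was at log2 −1.55 and PDF1.2 at −1.87, and BCAT4 was at −0.039 and −0.018 against the sets for taf4bint and the double mutant. Among the cell wall genes EXPA8 (2.84), EXPA4 (1.68) and EXPA15 (1.14) rose, 3 of 3, against 1, 0 and 0 with the other 3 Col-0 sets. All 3 Calvin cycle genes rose (SBPASE by log2 1.48, RCA by 0.41 and PRK 2.15-fold), as did 2 of 5 light reaction genes (LHCB4.2 by log2 1.79 ± 0.16 and ATPC1 2.14-fold). Against the other 3 Col-0 sets 0 genes of these 2 lists rose, while 2, 2 and 2 Calvin cycle genes and 5, 5 and 5 light reaction genes fell. COR15B (2.23) and COR15A (1.61) rose while LTI30 fell (−1.94). The heat gene AT5G48570 (1.28), CRT1b (0.89) and the reference gene GAPC2 (1.13) rose, and GI (−1.37), SWEET11 (−1.15), BZIP60 (−1.06) and EIN3 (−0.69) fell. Against at least 1 other Col-0 set GSTU20, IAA29, EXPA8, EXPA15, COR15B, LTI30, EIN3, GI, WRKY6 and EFR stood in the opposite direction. Of 69 plastid-encoded genes 26 fell and 4 rose, against 42 and 4, 22 and 23, and 55 and 0 with the Col-0 sets for taf4bint, the line and the double mutant. In all 3964 probe sets were higher and 2520 lower, 6484 in all, around a median shift of log2 +0.16, and the values as deposited gave 7049 higher and 906 lower. Of 46 named genes, 10 passed under every setting.

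The AB and ES4 changes in Col-0 correlated at 0.85 (Spearman 0.83) across probe sets, with the same 3 control arrays in both; genes are not independent replicates. Both raised 3074 probe sets against 1083 expected and both lowered 1936 against 455, while 14 and 30 were called in opposite directions against 688 and 715. Unchanged groups simulated against the shared control gave a correlation of 0.50, a covariance lower than the observed one by 1.02, and 0 shared calls. The simulated groups held the means of that control plus independent noise. They cannot show what a difference between sets of arrays would add to both responses. The other uninfected Col-0 sets differed from that control in 7601 to 7867 probe sets. With AB against its first control and ES4 against the Col-0 sets for taf4bint, for the line and for the double mutant, the correlation dropped to 0.30, 0.20 and 0.12, with 1618, 1257 and 878 probe sets higher in both and 949, 772 and 641 lower in both. Among genes of opposite direction, picked after the values were seen, COR15A was at log2 −2.78 with AB and 1.61 with ES4, and SWEET4 at −1.73 and 1.54. COR15A kept both directions against every Col-0 set. Its ES4 rise did not pass against the set for the line (1.09), nor its AB fall against the set for the double mutant (−0.69). COR15B was at −2.38 with AB and 2.23 with ES4, but its ES4 value was −0.80 and −2.14 against the Col-0 sets for taf4bint and the line.

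The 4 sets of uninfected Col-0 arrays differed from each other in 11083 of 15922 probe sets (69.6%) by limma's moderated F test with Benjamini-Hochberg adjustment, with a median range of log2 1.19 and 8247 calls above a range of log2 1. LHCB4.2 had a signal of 4632 ± 574 (mean ± SD) in the Col-0 set for taf4bprm and 30720 ± 329, 34635 ± 4238 and 29781 ± 1682 in the sets for taf4bint, the line and the double mutant. PRK stood at 3293 ± 344, 13343 ± 1745, 13561 ± 1161 and 14439 ± 3993, and PDF1.2 at 375 ± 441, 2524 ± 3344, 24368 ± 21092 and 237 ± 206. AT5G48430 stood at 4545 ± 478 in the set for taf4bprm and at 55.1 ± 21.3, 9.40 ± 0.912 and 118 ± 66.5 in the others. GRX480 averaged 372, 10378, 308 and 2057, and PUB19 41.4, 5311, 30.2 and 1521. The set for taf4bprm differed from the other sets in 7752, 7601 and 7867 probe sets, while the other 3 differed among themselves in 3262, 3438 and 4453.

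**Figure D4:**
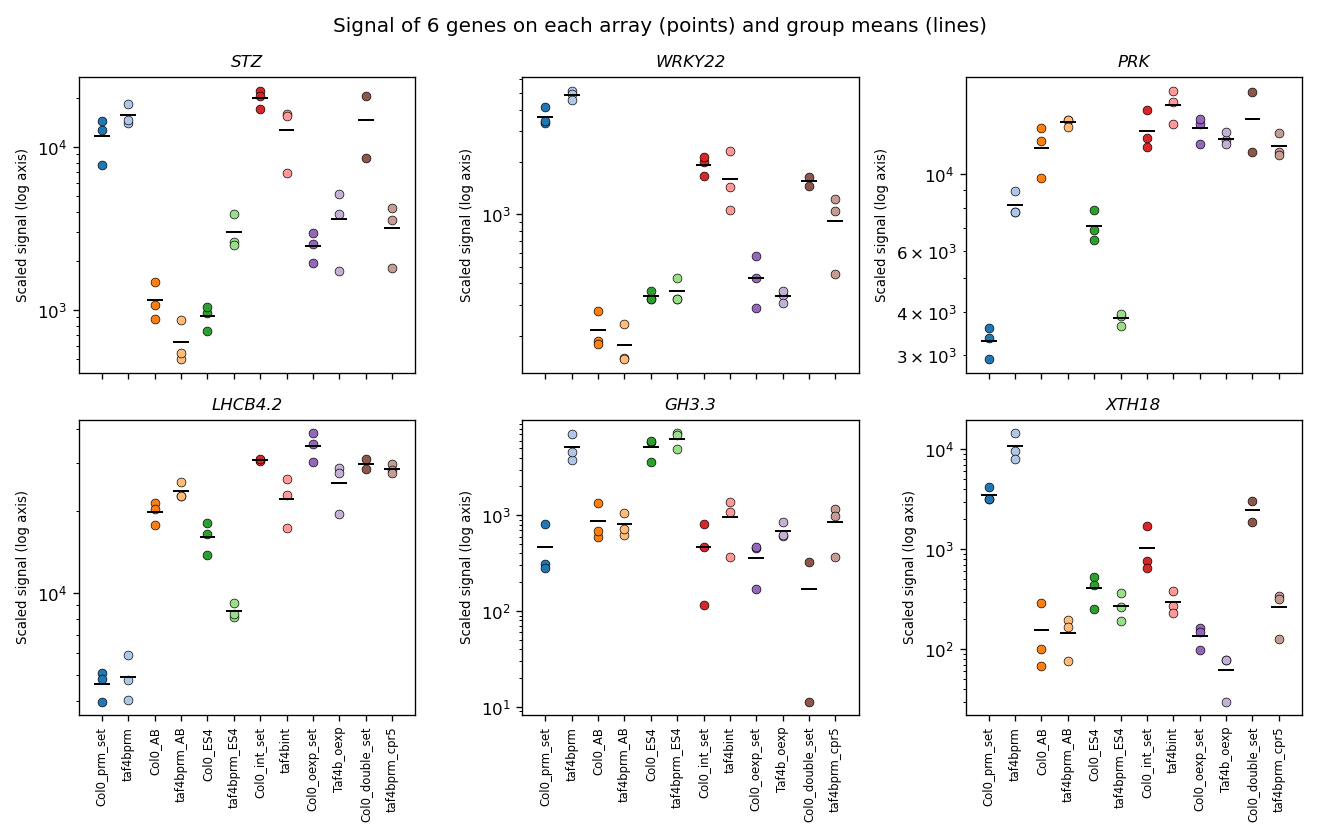
Scaled signal (log axis) of STZ, WRKY22, PRK, LHCB4.2, GH3.3 and XTH18 in the 12 groups. Points are arrays and lines are group means.

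Against all 4 Col-0 sets in turn, 1357 of the 7222 AB calls (18.8%) passed in 1 direction, 822 higher and 535 lower, and 1413 (19.6%) were called in the opposite direction against at least 1 set. For ES4, 989 of 6484 (15.3%) passed in 1 direction, 595 higher and 394 lower, and 1407 (21.7%) were called opposite. Some of the immune signalling genes stayed past the threshold: with AB, STZ was at log2 −3.33, −4.14, −1.13 and −3.57 against the sets for taf4bprm, taf4bint, the line and the double mutant, WRKY53 at −3.18, −4.12, −1.43 and −3.55, WRKY22 at −4.07, −3.15, −0.96 and −2.84 and SAG101 at −2.63, −2.85, −1.71 and −1.95. WRKY6 did not stay (log2 −2.31, −0.85, −0.27 and 0.53 with AB), nor did WRKY22 with ES4, at log2 −0.30 against the set for the line. Salicylic acid genes fell with AB in 3, 3, 2 and 3 cases, and pattern-triggered immunity genes fell in 2, 2, 1 and 1 cases and rose in 1 case against the set for the double mutant. LTI30 (−5.71, −4.81, −4.95 and −2.94) and COR15B (−2.38, −5.41, −6.75 and −3.75) stayed lower with AB, and AT1G53540 (2.14, 4.51, 5.93 and 4.37) stayed higher. GH3.3 stayed higher with ES4 at 3.56, 3.78, 3.89 and 6.05. PYK10 (5.52, 7.05, 7.48 and 3.72), AT3G33066 (7.11, 8.17, 7.38 and 4.98) and the osmotin OSM34 (3.64, 6.07, 4.79 and 3.86), picked after the values were seen, were higher with AB throughout. The rise of Calvin cycle and light reaction genes was limited to the set for taf4bprm with either infection. Heat genes rose with AB in 2, 4, 4 and 4 cases and with ES4 in 1, 3, 3 and 3 cases.

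**Figure D5:**
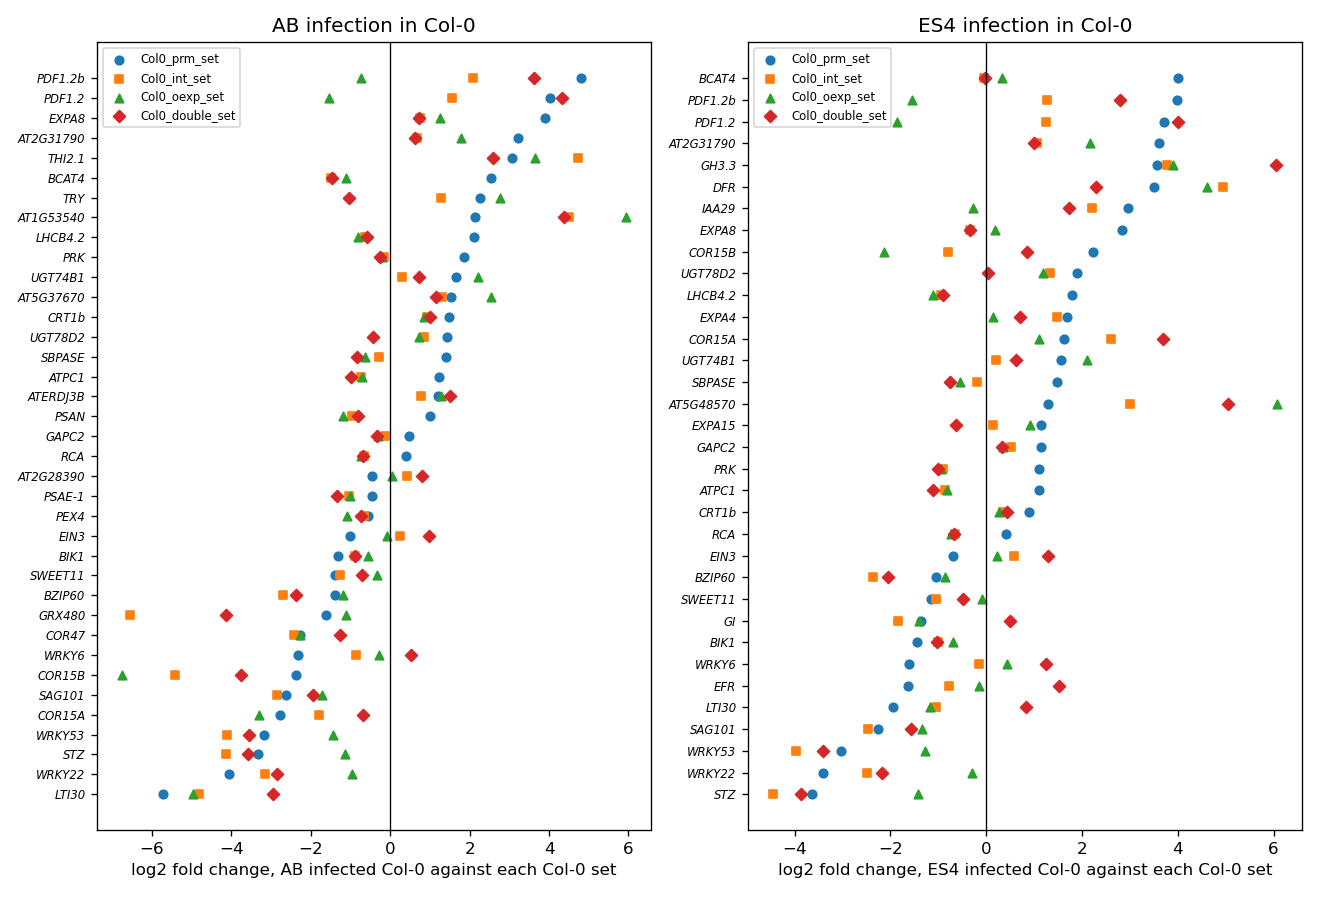
Log2 fold change (horizontal) of list genes in infected Col-0 against each of the 4 Col-0 sets, for AB and ES4. Each point is a gene against 1 Col-0 set, with the control set shown by marker and color.

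Infection AB in taf4bprm lowered WRKY22 27.3-fold (log2 −4.77 ± 0.28, adjusted p = 2.6e-13, n = 3 against 3), STZ 25.1-fold (−4.65 ± 0.37), WRKY53 by log2 −3.26 ± 0.41, SAG101 by −3.21 ± 0.28, BIK1 by −1.93 and WRKY6 by −1.60. Salicylic acid and pattern-triggered immunity genes each fell in 2 of 3 cases, with camera adjusted p = 0.0168 for both, and adjusted p = 0.131 with an estimated correlation. All 4 ABA and cold genes fell (LTI30 −5.78 ± 0.54, COR47 −3.79 ± 0.25, COR15B −3.34), with camera adjusted p = 1.8e-04, and adjusted p = 0.131 with an estimated correlation. Auxin genes fell in 2 of 3 cases: GH3.3 by log2 −2.64 ± 0.72 and IAA29 by −2.15. XTH18 fell 74.0-fold (−6.21 ± 0.46), 1 of 4 XTH genes that fell, and AT1G33760 (at least 95.4-fold, −6.58), AT1G15010 (−6.43), AT1G22810 (−5.70) and AT2G38240 (−5.59) were also among the lowest. AT3G33066 (6.90 ± 1.11), AT4G19430 (6.51), AT3G21670 (66.3-fold, 6.05 ± 0.40), AT1G13650 (5.74), AT1G64500 (5.74) and AFR (5.57 ± 0.48) rose most. Uninfected taf4bprm had AT3G21670, AT1G13650, AT1G64500 and AFR at signals of 34.5, 5.13, 18.3 and 9.47. In uninfected taf4bint these genes stood at 1161, 331, 132 and 191. AT3G33066 and AT4G19430 were not higher in taf4bint (26.6 and 56.8, against 37.7 and 63.3). XTH18 averaged 10773 in uninfected taf4bprm and 62.1 to 3531 in the other uninfected groups. Array-set differences may thus carry part of these changes. EXPA8 (5.01 ± 0.54), THI2.1 (4.56 ± 1.03), PDF1.2b (4.33), PDF1.2 (4.32 ± 1.03), AT2G31790 (3.59), BCAT4 (3.11), UGT74B1 (2.42) and UGT78D2 (2.35) rose, as did the heat genes AT1G53540 (3.47) and AT5G37670 (3.47), CRT1b (1.91 ± 0.20) and ATERDJ3B (1.78). LHCB4.2 (2.28 ± 0.16), PRK (0.79 ± 0.14), ATPC1 (0.68) and AT2G04400 (0.98) rose, with LHCB4.2 at a signal of 23605 under AB and 4907 in uninfected taf4bprm, where the other uninfected groups apart from the paired Col-0 set averaged 22107 to 34635. Under AB SWEET11 (−1.45), GI (−1.13), BZIP60 (−1.07) and EIN3 (−1.06) fell. Of the families chosen afterwards, 10 of the same 13 cytochromes P450, mostly CYP71B genes, rose (camera adjusted p = 0.0324 with an estimated correlation, CYP71B26 4.21 ± 0.33). In the same way 5 of 7 calmodulin-like genes fell (median −2.39, camera adjusted p = 0.0102 with an estimated correlation). Of 12 mitochondrion-encoded genes 11 rose, with cox2 at log2 2.57 ± 0.35, and camera gave adjusted p = 0.124 with an estimated correlation. By limma's moderated test 5053 probe sets were higher and 3129 lower, 8182 in all, around a median shift of log2 +0.23, and the values as deposited gave 10622 higher and 764 lower.

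Infection ES4 in taf4bprm raised AT3G02480 342-fold (log2 8.42), AT5G39520 by log2 7.23, UGT76E12 by 7.08, AT1G09500 by 6.85, the U-box ligase PUB19 by 6.58, AT3G21670 by 6.40 and the sugar transporter SAG29 by 4.28 ± 0.76. Uninfected taf4bprm had these genes at signals of 31.6, 73.8, 9.36, 54.9, 43.3, 34.5 and 21.1, in that order. They stood at 289, 3986, 312, 3511, 1553, 1161 and 67.1 in uninfected taf4bint, so array-set differences may carry part of these rises. For AT3G02480 and UGT76E12 the SD in taf4bint (422 and 332) exceeded the mean, so the doubt is weak there. With ES4 in Col-0, AT3G02480 was higher against all 4 Col-0 sets, by log2 3.29, 3.71, 5.13 and 3.86. PDF1.2b (5.60 ± 0.92), PDF1.2 (5.23), the auxin gene WES1 (1.86), COR15A (2.00), COR15B (1.49), AT1G53540 (3.04), AT5G37670 (1.09), BCAT4 (2.43), AT2G31790 (1.90), AT2G04400 (1.11), EXPA8 (1.65), GAPC2 (2.30-fold) and LHCB4.2 (0.82) also rose, as did UGT74B1 (2.00-fold) and UGT78D2 (2.46-fold). AT5G62360 fell 281-fold (−8.14 ± 0.40, adjusted p = 4.0e-15, n = 3 against 3), followed by AT1G33760 (−6.32), AT4G32800 (−5.47), AT4G10270 (−5.31), XTH18 (−5.28 ± 0.46) and AT3G05320 (−5.12). All 3 Calvin cycle genes fell (SBPASE −1.32 ± 0.28, PRK −1.09 ± 0.14, RCA −0.50), but the list did not pass camera (adjusted p = 0.0775, and adjusted p = 0.358 with an estimated correlation). Of 5 light reaction genes 3 fell, with PSAN at −2.17 ± 0.19 (adjusted p = 2.3e-10) and PSAE-1 at −1.06, and LHCB4.2 rose, and this list did not pass camera either (adjusted p = 0.0912, and adjusted p = 0.461 with an estimated correlation). WRKY22 (−3.74 ± 0.28), SAG101 (−3.48 ± 0.28), WRKY53 (−3.11), STZ (−2.40 ± 0.37), BIK1 (−1.63), SWEET11 (−1.47), LTI30 (−1.32) and EXPA4 (−1.19) fell. WRKY22 averaged 361 here, and 338 and 432 in the uninfected overexpression line and its Col-0 set. STZ averaged 3003 here, and 3599 and 2476 in those groups. Array-set differences may thus carry part of these 2 falls. WRKY53, at 317, lay below every uninfected group, the lowest of which averaged 452. In the families chosen afterwards 15 of 31 UDP-glycosyltransferases rose and 1 fell, with UGT76E11 at log2 3.93 ± 0.33 and UGT73B1 at 3.80 ± 0.35, 8 of 13 cytochromes P450 rose (CYP71B26 4.74 ± 0.33) and 4 of 5 XTH genes fell (median −3.99). In all 3828 probe sets were higher and 3358 lower, 7186 in all, and the values as deposited gave 4620 higher and 1628 lower.

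With AB infection in both genotypes, taf4bprm and Col-0 differed in 15 probe sets, 2 higher and 13 lower, with 1455 under an unadjusted p of 0.05. AT4G33980 was 3.36-fold lower in taf4bprm (log2 −1.75 ± 0.28, adjusted p = 0.0052, n = 3 against 3), FDH lower by log2 −1.18 ± 0.20 (adjusted p = 0.0058), AT1G69840 by −1.18 ± 0.21 (adjusted p = 0.010), AT4G19200 2.00-fold, the tonoplast sugar transporter TMT1 by log2 −0.98 and AT5G19250 by −0.91. No member of any list written beforehand passed. Of the plastid-encoded genes 0 passed, and 15 rose when adjusted over the list alone, with a median of log2 0.41. Camera gave the light reaction list adjusted p = 0.0175 and the ethylene list adjusted p = 0.0386, and both had adjusted p = 0.449 with an estimated correlation. Quantile normalization gave 11 higher and 35 lower, and with only the 6 arrays compared 1121 were called, 564 higher and 557 lower. Leaving out 1 array gave 1 to 48 calls, and 0 of 6 named genes passed under every setting.

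With ES4 infection in both genotypes, taf4bprm and Col-0 differed in 3815 probe sets, 1369 higher and 2446 lower, around a median shift of log2 −0.13. LEA4-5 was 45.6-fold higher in taf4bprm (log2 5.51 ± 0.75, adjusted p = 9.6e-06, n = 3 against 3), AT3G02480 higher by log2 4.69, AT4G37220 by 4.61, AT4G28140 by 3.51, AT1G05340 by 3.47, AT1G24600 by 3.43 and SAG29 by 3.09 ± 0.76. STZ (1.70 ± 0.37), BZIP60 (0.91), COR47 (0.83) and the reference gene AT2G28390 (0.69) were higher too. AT5G55450 was 29.4-fold lower (−4.88 ± 0.61), with AT1G06000 (−4.25), AT5G03350 (−4.18 ± 0.49), AT5G12940 (−3.89), TBL26 (−3.24) and AT1G29660 (−3.20) next. Photosynthesis genes were lower: 4 of 5 light reaction genes (PSAN −1.70 ± 0.19, adjusted p = 6.7e-07; LHCB4.2 −0.90 ± 0.16; ATPC1 −0.56) with camera adjusted p = 0.0047, and adjusted p = 0.369 with an estimated correlation. Calvin cycle genes were lower in 2 of 3 cases, 3 of 3 adjusted over the list alone (SBPASE −1.58 ± 0.28, PRK −0.88 ± 0.14), with camera adjusted p = 0.0145, and adjusted p = 0.369 with an estimated correlation. Glucosinolate genes AT2G31790 (−1.63), UGT74B1 (−1.60 ± 0.24) and BCAT4 (−1.53), the pigment genes DFR (−2.65) and UGT78D2 (−0.98) and the expansins EXPA8 (−1.93) and EXPA4 (−1.64) were lower. Of 8 autophagy genes 3 were higher, 6 adjusted over the list alone, with ATG8H at log2 2.13 ± 0.35. The values as deposited gave 434 higher and 2387 lower, and with only the 6 arrays compared 6668 probe sets were called.

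The AB response of taf4bprm differed from that of Col-0 in 447 probe sets when the difference itself was tested, 236 higher and 211 lower, with 2631 under an unadjusted p of 0.05. AT3G51470 (log2 −4.24 ± 0.54, adjusted p = 6.1e-05, n = 3 in each of 4 groups), GH3.3 (−3.61 ± 1.02, adjusted p = 0.049), AT2G37580 (−3.51), AT4G34950 (−3.30), AT4G27720 (−2.63) and EXLA2 (−2.63) responded lower in taf4bprm. Each value equals the genotype difference under AB minus that without infection. Without infection GH3.3, AT4G34950 and EXLA2 were higher in taf4bprm by log2 3.55, 2.21 and 2.88, while only 15 probe sets differed under AB. Much of these values thus restates the uninfected difference with its sign reversed. PRK, 1 of 3 Calvin cycle genes, responded lower by log2 −1.05 ± 0.20 (adjusted p = 0.0045) and COR47 by −1.51 ± 0.36. Camera gave the Calvin cycle list adjusted p = 0.0202, and adjusted p = 0.488 with an estimated correlation. AT3G56260 (4.16 ± 0.83), AT2G07777 (3.17), SP1L4 (3.15), AT4G33440 (3.12 ± 0.40), AT5G26200 (2.97) and AT5G42250 (2.92) responded higher. Of 13 cytochromes P450, 3 responded higher, 6 adjusted over the list alone (median log2 1.07; adjusted p = 0.0299 with an estimated correlation), with CYP71B36 at 2.71 ± 0.66 and CYP71B35 at 2.50 ± 0.62. The values as deposited gave 8 higher and 37 lower. With only the arrays compared 1235 were called, and leaving out 1 array gave 225 to 411. Of 100 groupings of the arrays, the real one included, 8 gave as many calls.

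The ES4 response differed between taf4bprm and Col-0 in 4166 probe sets, 1792 higher and 2374 lower, around a median of log2 −0.10. LEA4-5 (log2 6.40 ± 1.07), AT1G19530 (5.74), AT2G35730 (5.41), AT1G30700 (5.31), AT3G18250 (5.29) and AT3G02480 (5.13) responded higher in taf4bprm, as did SAG29 (3.16), WRKY6 (2.30), AT5G37670 (1.60), BZIP60 (1.34), AT2G04400 (1.24) and AT2G28390 (0.70). AT5G55450 (81.8-fold, −6.35 ± 0.87), AT5G12940 (−5.54), AT2G37580 (−5.44), AT3G51470 (−5.38 ± 0.54), AT4G10390 (−4.98) and AT2G36885 (−4.83) responded lower. All 5 light reaction genes responded lower (PSAN −2.37 ± 0.27, ATPC1 −1.35 ± 0.19, LHCB4.2 −0.97; median −0.97), and all 3 Calvin cycle genes did (SBPASE −2.80 ± 0.40, adjusted p = 1.1e-05; PRK −2.19 ± 0.20, adjusted p = 3.4e-08; RCA −0.90). Camera gave both lists adjusted p = 2.8e-04, and adjusted p = 0.153 with an estimated correlation. Auxin genes GH3.3 (−3.23 ± 1.02) and IAA29 (−3.02 ± 0.73) responded lower, 2 of 3, as did EXPA4 (−2.87), AT2G31790 (−1.70) and SAG101 (−1.23). GH3.3 was higher by log2 3.55 in uninfected taf4bprm, so its value here largely restates that difference with its sign reversed. Autophagy genes responded higher in 4 of 8 cases, with ATG8H at 2.08 ± 0.49 and ATG8B at 1.94 ± 0.34. The values as deposited gave 678 higher and 1763 lower.

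The change in the double mutant differed from that in taf4bprm in 3922 probe sets, 2531 higher and 1391 lower, around a median shift of log2 +0.17, each against its own Col-0 set. AT4G12500 (119-fold, log2 6.90 ± 1.06), AT1G26420 (6.51 ± 1.18), AT4G12490 (6.48), AT3G21080 (6.30), AT3G18250 (5.49) and AT2G17740 (5.46) were higher. EFR (2.64), WRKY6 (2.47), WES1 (2.43), COR15A (2.33), AT2G04400 (2.18 ± 0.41), GI (2.06), EIN3 (1.28) and AT2G28390 (1.14) were higher as well. AT4G27654 (−5.53 ± 0.65), AT1G33760 (−5.40), AT3G02840 (−5.37), AT1G19210 (−5.02), XTH18 (−4.87) and ORA47 (−4.82) were lower. All 3 Calvin cycle genes were lower (SBPASE −2.48 ± 0.42, PRK −1.55 ± 0.22, adjusted p = 1.2e-05, RCA −1.02) with camera adjusted p = 4.8e-04, and adjusted p = 0.171 with an estimated correlation. Each value subtracts the change in taf4bprm, where these genes, ATPC1 and PSAN rose, a rise that turned against all uninfected Col-0 arrays. PRK averaged 12060 in the double mutant and 14439 in its Col-0 set, but 8171 in taf4bprm and 3293 in its Col-0 set. The PRK value thus largely restates the rise in taf4bprm with its sign reversed. Light reaction genes were lower in 3 of 5 cases (ATPC1 −1.70 ± 0.20, PSAN −0.84, PSAE-1 −0.84) with camera adjusted p = 0.0098, and adjusted p = 0.465 with an estimated correlation. STZ (−2.61 ± 0.56), TRY (−2.83), BZIP60 (−1.14) and UGT78D2 (−1.04) were lower. Plastid-encoded genes were lower in 64 of 69 cases (median log2 −1.76; adjusted p = 0.0328 with an estimated correlation), with ndhD at −4.47 ± 0.33 and rpl33 at −4.25 ± 0.46. CYP71B23 was higher by log2 4.86 ± 0.79, 1 of 6 P450 genes that were. Without 1 or the other control array of the double mutant AT3G18250, EFR, WRKY6, WES1, COR15A, GI, PSAN, TRY, BZIP60 and UGT78D2 no longer passed. With only the 11 arrays compared 2024 probe sets were called, and the values as deposited gave 328 higher and 1157 lower.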

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

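The tests of the scaling and of single arrays under ES4, of the other Col-0 sets for the plastid-encoded genes, and of infection against each Col-0 set were chosen only after the results were seen. The tests of 1 control array and of the scaling for the plastid-encoded genes, of the actin ratio and of regrouped arrays were written beforehand.

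Plastid-encoded genes were lower in the double mutant, and in the test of the difference itself 3922 probe sets changed differently in the double mutant than in taf4bprm. Without either of the 2 control arrays at least 53 of 69 genes stayed lower, which argues against a single control array as the cause. After quantile normalization the median lay log2 −1.68 from that of all probe sets, which argues against scaling as the whole cause. With the actin ratio as a covariate 44 genes stayed lower. The slope of this covariate comes only from variation within groups, so it cannot decide on RNA integrity. The ratio averaged 6.95 in the double mutant and 18.3 in its Col-0 set. A high plastid level in this 1 Col-0 set and a true loss in the mutant cannot be told apart, because against the other 3 Col-0 sets the lowest median was log2 −0.96 but the highest was −0.11. No regrouping was run for these 5 arrays.

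Between taf4bprm and Col-0, 3815 probe sets differed under ES4 and 15 under AB, or 6668 and 1121 with only the arrays compared, so the size of the gap depends on the fit, and tests of the difference between responses gave 4166 probe sets for ES4 and 447 for AB. Scaling and single arrays are unlikely sources of this gap, since quantile normalization left 3581 calls under ES4 and leaving out any 1 array left at least 2603. With the actin ratio as a covariate 3693 calls were left, but its slope comes only from variation within groups. The ratio averaged 4.49 in Col-0 and 3.40 in taf4bprm under ES4, and 3.84 and 6.44 under AB. The smaller gap in the ratio went with more calls, which argues against RNA integrity as read by this ratio. No test separates genotype from a separate growth or processing occasion of an infected group. Of 100 groupings of the arrays, the real one alone gave as many calls as the ES4 response difference (highest other 2328). Labels were redrawn within infected and within uninfected arrays, so any genotype or array-set difference could give this result. A random split of these arrays is thus an unlikely source of the count, but chance between plants or occasions was not tested. For the AB response difference 8 of 100 groupings, the real one included, gave as many calls, with a highest other of 1120. Chance is thus not excluded, and a maximum above the real count of 447 may reflect other structure among the samples.

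Infection results in Col-0 changed with the Col-0 set used as control. Only 18.8% of the AB calls passed in the same direction against all 4 sets, so most AB calls depend on the set used as control. The sets for taf4bint and the line were deposited scaled, unlike the infected arrays and the sets for taf4bprm and the double mutant. Every array was scaled alike here. The sets for taf4bprm and the double mutant, both deposited unscaled, differed in 7867 probe sets. The set for the double mutant differed from the sets for taf4bint and the line in 3438 and 4453. These counts argue against the deposited scaling as the source of the differences between Col-0 sets. With the actin ratio as a covariate 8989 probe sets still differed between the sets. Its slope comes only from variation within groups, so this cannot decide on RNA integrity. The ratio averaged 4.55 in the set for taf4bprm and 14.8 to 20.9 in the others. That set differed from the others in 7601 to 7867 probe sets, against 3262 to 4453 among the others. A separate growth or processing occasion for each set is a possible explanation that these arrays do not separate from infection. For AB, PRK moved from log2 1.85 to −0.17 when the Col-0 set for taf4bint served as control, BCAT4 from 2.54 to −1.49, and PDF1.2b from 4.80 to −0.74 with the set for the overexpression line.

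Each comparison of 2 groups of 3 arrays allows 10 regroupings, which are too few to exclude chance or not. The real grouping was in each case the only 1 with as many calls, with a highest other count of 24 in taf4bprm, 23 in taf4bint, 363 in the overexpression line, 0 for AB and 1 for ES4 in Col-0, 0 and 2 for AB and ES4 in taf4bprm, and 0 between the genotypes under either infection.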

How the results depend on the processing

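Of the settings below, the fit to the values as deposited was chosen after the results were seen, and all others were chosen before the data were examined. With the values as deposited, the counts were 725 in taf4bprm, 140 in taf4bint, 279 in the overexpression line, 1686 in the double mutant, 12290 for AB in Col-0, 4 between the genotypes under AB, 45 for the AB response difference, 2441 for the ES4 response difference and 1485 for the double mutant difference. The deposited arrays differed in trimmed mean by construction, by up to 8.35 times among those not scaled, so these counts carry the scaling. With only the arrays compared, the counts were 14 in taf4bint, 10 in the overexpression line, 121 in the double mutant, 1121 between the genotypes under AB, 6668 under ES4, 1235 for the AB response difference, 2024 for the double mutant difference and 36 calls by camera against 21 among the lists written beforehand, 0 of which held with an estimated correlation. The infected groups had replicate correlations of 0.959 or more. The SD of log2 differences between 2 replicates was 0.306 to 0.526 there. It was 0.753 to 0.923 in taf4bint, 0.651 to 0.887 in the overexpression line and 1.13 in the Col-0 set for the double mutant. A spread pooled over all groups is wide for the former and narrow for the latter. The loss of residual degrees of freedom in fits of only the arrays compared was not separated from this. Without the filter, camera made 36 calls among those lists and the correlation of AB with ES4 was 0.82. Quantile normalization raised the count under AB to 46 from 15 and turned PSAE-1 in the double mutant to log2 0.047. Apart from the values as deposited and the replicate spread given for fits of only the arrays compared, the cause of these moves was not tested. Changing the pseudocount to none or to the 25th percentile moved no count by more than 1.5 times. Signal over background limits what the lowest-signal genes can give, because a log2 change is damped as the signal nears the pseudocount of 5.56.

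Against all 11 uninfected Col-0 arrays the counts were 4530 in taf4bprm, 1258 in taf4bint, 1451 in the double mutant, 4668 for AB and 3756 for ES4. In log2 change, this control gave the opposite direction for AT2G37580 (−0.028), PRK (−0.18), SBPASE (−0.20), ATPC1 (−0.67), PSAN (−0.80), RCA (−0.28) and LHCB4.1 (−0.12) in taf4bprm. The opposite direction also came for EIN3 (−0.037) and TRY (0.17) in the double mutant. For AB in Col-0 the direction turned in BCAT4 (−0.29), SBPASE (−0.012), ATPC1 (−0.24), PSAN (−0.46), GAPC2 (−0.054), RCA (−0.39) and AT2G28390 (0.15). For ES4 in Col-0 the direction turned in COR15B (−0.041), LHCB4.2 (−0.24), PRK (−0.39), ATPC1 (−0.36), RCA (−0.39) and EIN3 (0.27).

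With the Col-0 set for taf4bint as control, the AB direction turned in BCAT4 (−1.49), LHCB4.2 (−0.64), PRK (−0.17), SBPASE (−0.27), ATPC1 (−0.73), PSAN (−0.97), GAPC2 (−0.14), RCA (−0.65), AT2G28390 (0.43) and EIN3 (0.26). For ES4 the same control turned the direction in BCAT4 (−0.039), EXPA8 (−0.33), COR15B (−0.80), LHCB4.2 (−0.94), SBPASE (−0.20), PRK (−0.91), ATPC1 (−0.86), RCA (−0.64), EIN3 (0.58), AT2G17740 (0.43) and AT5G48430 (0.046). With the Col-0 set for the overexpression line as control, the AB direction turned in PDF1.2b (−0.74), PDF1.2 (−1.55), BCAT4 (−1.12), LHCB4.2 (−0.80), PRK (−0.19), SBPASE (−0.63), ATPC1 (−0.70), PSAN (−1.18), GAPC2 (−0.32), RCA (−0.75) and AT2G28390 (0.043). For ES4 the same control turned the direction in GSTU20 (−0.12), PDF1.2b (−1.55), PDF1.2 (−1.87), IAA29 (−0.28), COR15B (−2.14), LHCB4.2 (−1.11), SBPASE (−0.56), PRK (−0.94), ATPC1 (−0.83), RCA (−0.74), EIN3 (0.23), WRKY6 (0.43), AT2G17740 (0.66) and AT5G48430 (2.01). With the Col-0 set for the double mutant as control, the AB direction turned in BCAT4 (−1.47), TRY (−1.05), LHCB4.2 (−0.59), PRK (−0.26), UGT78D2 (−0.43), SBPASE (−0.83), ATPC1 (−0.99), PSAN (−0.80), GAPC2 (−0.33), RCA (−0.67), AT2G28390 (0.79), EIN3 (0.97) and WRKY6 (0.53). For ES4 the same control turned the direction in BCAT4 (−0.018), EXPA8 (−0.34), LHCB4.2 (−0.90), SBPASE (−0.76), EXPA15 (−0.63), PRK (−1.01), ATPC1 (−1.11), RCA (−0.67), EIN3 (1.29), GI (0.50), WRKY6 (1.24), EFR (1.52), LTI30 (0.83) and AT2G17740 (0.32). Over all settings but the values as deposited, 5303 alternative values of named genes gave 4654 with the same direction and call, 553 past the threshold no longer and 96 in the opposite direction.

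Leaving out 1 array at a time gave 1755 to 2157 calls in taf4bprm, 230 to 758 in taf4bint, 101 to 2162 in the overexpression line, 2965 to 4675 in the double mutant, 6025 to 6732 for AB and 5432 to 6065 for ES4 in Col-0, and 7091 to 7564 and 6334 to 6528 for AB and ES4 in taf4bprm. It gave 1 to 48 calls between the genotypes under AB, 2603 to 2869 under ES4, 225 to 411 for the AB response difference, 3466 to 4074 for the ES4 response difference, 3077 to 4735 for the double mutant difference and 20 to 30 list calls. The correlation of taf4bprm with taf4bint ranged from −0.094 to 0.13 and turned negative without taf4bprm replicate 1 or taf4bint replicate 1, and that of AB with ES4 ranged from 0.82 to 0.86. The taf4bint count moved by more than 1.5 times without replicate 2 (237) or 3 (230) of its Col-0 set. In the overexpression line every array did so: 478, 494 and 450 without Col-0 replicates 1, 2 and 3, and 146, 101 and 2162 without replicates 1, 2 and 3 of the line. Under AB the count was 5, 9 and 1 without infected Col-0 replicates 1, 2 and 3, and 3, 5 and 48 without infected taf4bprm replicates 1, 2 and 3. The AB response difference fell to 279 without replicate 2 of the Col-0 set for taf4bprm, to 225, 259 and 256 without infected Col-0 replicates 1, 2 and 3, and to 227, 231 and 288 without infected taf4bprm replicates 1, 2 and 3.

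A block for the replicate number gave 2589 calls in taf4bprm, 810 in taf4bint, 1102 in the overexpression line, 3515 in the double mutant, 7104 for AB and 6404 for ES4 in Col-0, 8067 and 7064 for AB and ES4 in taf4bprm, 17 and 3569 between the genotypes under AB and ES4, 416 and 4020 for the AB and ES4 response differences, 3908 for the double mutant difference, 11041 between the Col-0 sets and 23 list calls. Residuals of arrays with the same replicate number correlated from −0.12 to 0.25 over 13 comparisons, with 0 comparisons where every correlation was over 0.1, so the replicate numbers do not pair the arrays.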

Other observations

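The tests of list genes against each Col-0 set and of replicate 3 of the overexpression line were chosen only after the results were seen. The tests of the response differences were planned before the data were examined.

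Genes of rapid responses to handling or wounding may differ between the sets of arrays apart from infection. AT1G33760 was lower in 8 comparisons: taf4bint, the overexpression line, the double mutant, both infections of both genotypes, and the double mutant difference. In AB it stayed lower against all 4 Col-0 sets, at log2 −6.33, −7.66, −4.17 and −7.12, while 18.8% of all AB calls did. The hypothesis that uninfected leaves carried a handling response would be tested by quantitative PCR of STZ, WRKY53 and AT1G33760 in leaves frozen at fixed times after cutting.

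Photosynthesis genes of the nucleus form a second hypothesis. In taf4bprm without infection PRK rose by log2 1.31 and with ES4 it fell by log2 −1.09, and the difference of responses passed its own test at log2 −2.19. Because PRK turned to log2 −0.18 in uninfected taf4bprm against all 11 Col-0 arrays, the rise without infection could come from a low level in 1 Col-0 set. The ES4 fall uses no Col-0 array but shares the uninfected taf4bprm arrays with the rise, and these lay at 88.7 to 104 on principal component 2, beside that Col-0 set, against −3.48 to 2.32 for the ES4 arrays, so a difference between sets of arrays could carry it too. Infected and uninfected plants of both genotypes grown in 1 batch, with PRK, SBPASE and PSAN measured by quantitative PCR, would separate the 2 readings.

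Most of the 13 cytochrome P450 genes, mainly of the CYP71B subfamily, were lower in taf4bprm. A few had a higher response value for AB in that mutant, with CYP71B36 at log2 −2.45 and then 2.71. Both values use the same uninfected arrays, so a lower starting level and a larger response are largely 1 measurement, and no test here separates them. In the AB response difference 8 of 100 groupings, the real one included, gave as many calls, so this candidate needs new samples.

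Replicate 3 of the overexpression line correlated more with Col-0 (0.955) than with its own group (0.928), the former a mean of 3 arrays and the latter of 2, while replicates 1 and 2 did the reverse (0.929 against 0.960 and 0.917 against 0.952). Without it the count was 2162 and without replicate 2 of the line it was 101. A sample with weak expression of the transgene is a possible reading, which TAF4B measured by quantitative PCR on each RNA would test.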
